A study of Homo sapiens with 6 samples.

How the data were processed

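RNA of cultured human aortic endothelial cells was measured on 6 Affymetrix Human Gene 1.0 ST arrays, 3 for control medium and 3 for 500 µM L-homocysteine, each after 48 h. Per the labels' protocols, cells of passage 6 were grown to 80% confluence in medium M199 with 20% fetal calf serum, 50 µg/mL endothelial growth supplement and 50 µg/mL heparin. Groups and replicate numbers came from the sample titles. The series text also names a microRNA array, which is not analysed here.

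The authors deposited 1 log2 value per feature and array. Per the submitters' processing notes, the values were made with RMA and Partek; versions and settings are not given in the sources used here. RMA as usually run corrects background, makes the distributions of the arrays equal and sums up the probes of a feature. The deposited arrays were not fully equal, with interquartile ranges from 3.19 to 3.43, and the cause is not given. It gives no call of signal above background, so a low log2 value can be background. The deposited values lay between 2.65 and 14.13 with array medians from 7.17 to 7.28, as log2 values do, and were used without further normalisation. No scanner files were used here, so scan or slide batches were not tested.

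Features were named from the platform annotation. Of 26890 features, 19305 carried 1 gene symbol, 1750 several and 5835 none. The gene identifier of 19274 features with 1 symbol matched a current gene table of the assembly GRCh38.p14, no symbol needed an update, and 31 kept the platform's symbol. The 21055 features with at least 1 symbol were tested, with no filter on dim features. A gene was represented by the brightest of its own features over all 6 arrays, which mattered for 684 of 18374 genes. No gene was named from a feature with several symbols, except where this is stated. XIST and Y-linked genes were left out of everything listed.

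The difference of homocysteine minus control was fitted per feature with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings). P-values were 2-sided and adjusted by Benjamini-Hochberg over all features tested, with a threshold of 0.05. Changes are on the log2 scale. Errors given as SE come from the moderated fit unless they are named otherwise, and errors given as SD are between arrays. The median log2 change over all features was −0.014.

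Before the data were examined, 36 gene lists were fixed for this cell type and treatment, holding 885 different genes. Of these, 807 had a feature of their own, 31 lay only on features shared with other genes, and 47 are not analysed here. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 36 lists. Camera asks whether a list ranks above or below the other genes. Camera with an estimated correlation and fry were run beside it. Within each list, the limma p-values were also adjusted over the list alone.

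Genes named in the text were set by a rule made before the data were examined. It takes the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap. Loci without a proper gene name and small RNA genes took no place there. It adds up to 4 members of each list with the smallest p, and always CTH, MTR, MAT2A, AHCY, NOS3, EDN1, THBD, VCAM1, ICAM1, CCL2, CCNA2, DNMT1, HSPA5, ATF4, TRIB3, ASNS and HMOX1. CBS was also on that last list, but lay only on a feature shared with another gene and is not reported, and a further gene of it is not analysed here. A few genes outside the rule are named in the closing part and are marked there.

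The alternatives fixed beforehand were the replicate number as a block, quantile normalisation, median centring, filters at the 25th percentile and at the median level, all features including unnamed ones, array weights, a variance trend, each array left out, no moderation of the variance, a fold of 1.5 added to the threshold, and a test against a 1.2-fold change. For the lists, the trend was applied in camera, and the mean of all features of a gene was tried as well. The first residual component as a covariate, and leaving out control array 1 and homocysteine array 2 together, were chosen after seeing the data.

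The code was tested on simulated data with the design of this comparison, over 21055 features. Of 50 features changed by 0.5 on the log2 scale 19 were recovered, of 50 changed by 1 there were 47, and at 1.5 and 2 all 50 were. The simulation gave 169 calls, of which 3 were false. Its variances were drawn from the prior that limma fitted to the data, with normal noise and no differences in quality between arrays. These counts therefore test the code and do not measure false calls among the real arrays. Camera called 0 lists without a change and the 1 list that was shifted by 0.5. The simulated genes varied independently of each other. In the real data the estimated correlation between genes was 0.74 in the mitosis list and 0.8 in the histone list. Camera's false calls among correlated genes were therefore not tested.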

Results

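Human aortic endothelial cells (HAEC) are primary cells of the inner lining of the aorta. Gene expression was measured on 6 arrays, 3 of cultures given 500 µM L-homocysteine for 48 h and 3 of cultures given control medium. Homocysteine is a sulphur amino acid made from methionine. Per the labels, the dose was chosen to resemble the severe excess seen when cystathionine beta-synthase, the enzyme that removes homocysteine, is deficient. Each array gave 1 log2 value for each of 26890 features, of which 21055 carried at least 1 gene symbol. The array medians lay between 7.17 and 7.28. Correlations between arrays lay between 0.9897 and 0.9963 across features, which are not independent replicates, and no pair of arrays held identical values. The labels call the samples biological replicates without saying whether they came from separate donors or cultures. The p-values therefore measure the spread between these samples, and the number of arrays limits the precision.

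The comparison asks which transcripts differ between endothelial cells exposed to homocysteine and cells in control medium. The largest rise was that of PMCH, the precursor of melanin-concentrating hormone, which was 6.35-fold higher after homocysteine. Transcripts of MMP1, a collagenase of the extracellular matrix, and of CXCR4, a chemokine receptor, also rose. The largest fall was that of IL33, a nuclear cytokine of endothelial cells. ENTPD1, an ectoenzyme that breaks down extracellular ATP and ADP, fell as well. In all, 108 genes passed limma's test at an adjusted p under 0.05, with 75 higher and 33 lower after homocysteine.

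PMCH went from a log2 value of 6.22 ± 0.06 in control cells to 8.89 ± 0.30 after homocysteine (SD, n = 3 each), a rise of 2.67 (SE 0.14, adjusted p = 0.000154 by limma). The control level may be background, in which case the fold is a lower bound. MMP1 rose by 1.59 on the log2 scale (SE 0.19, adjusted p = 0.0123). GKN2, a gastrokine first known from the stomach, rose by 1.55 from a low level of 4.53. TRIM16, a ubiquitin ligase of the tripartite motif family, rose by 1.36, and a feature shared by TRIM16 and its near copy TRIM16L was higher by 1.08. RBM24, an RNA-binding protein, rose by 1.34, and CXCR4 rose by 1.19. CHRNA1, a subunit of the muscle acetylcholine receptor, rose by 1.13. The transcriptional repressor PRDM1 rose by 1.01, and GFM1, a mitochondrial translation elongation factor, rose by 1.00. GJA4, an arterial gap junction protein, rose by 0.98. The membrane protein TMEM140 rose by 0.97 and the lipid phosphatase PLPP6 by 0.95.

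IL33 fell by 1.57 on the log2 scale, from 8.03 to 6.46 (SE 0.17, adjusted p = 0.00925). LRRC17, a leucine-rich repeat protein, fell by 1.31. SULT1B1, a cytosolic sulfotransferase, fell by 1.30 from a high level of 11.44. The ATP-binding cassette transporters ABCA9 and ABCA6 fell by 1.22 and 0.99. POGLUT3, which adds glucose to epidermal growth factor-like repeats, fell by 1.10, and LMF1, needed for lipase maturation, fell by 1.08. The secreted metalloproteases ADAMTS18 and ADAMTS1 fell by 1.08 and 0.98. ENTPD1 fell by 0.98 (SE 0.09, adjusted p = 0.00517). RPL22L1, a relative of a ribosomal protein, fell by 0.97. IMPDH2, which catalyses the first committed step of guanine nucleotide synthesis, fell by 0.96. The 24 genes of these largest rises and falls had adjusted p-values between 0.000154 and 0.0406.

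**Figure D1:**
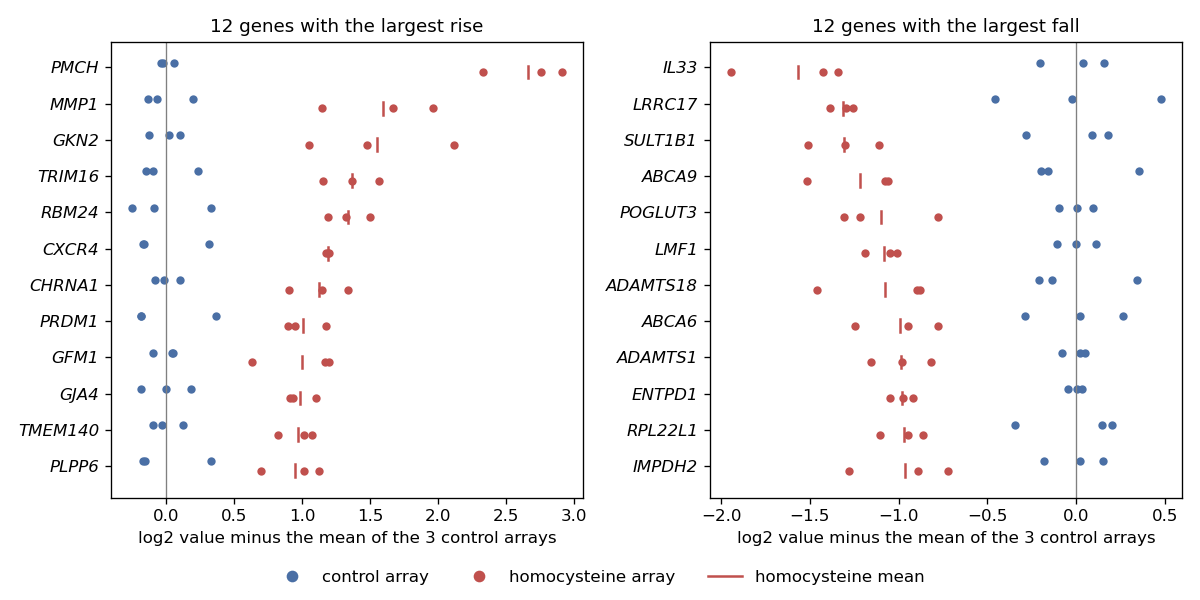
Each point is 1 array, drawn as its log2 value minus the mean of the 3 control arrays, for the 12 genes with the largest rise (left) and the 12 with the largest fall (right) among those past the threshold. Blue points are control arrays, red points are homocysteine arrays and red lines are the homocysteine means. Only genes whose groups do not overlap were chosen, so no control point overlaps the homocysteine points of its gene. PMCH lies farthest out at a mean of 2.67.

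The threshold was passed by 121 features, 79 higher and 42 lower, of which 6 were shared by several symbols. Without limma's moderation, which draws on the variance of all features, 0 features passed. Among the 108 genes, 17 changed at least 2-fold, 9 upwards and 8 downwards. All 108 had homocysteine values entirely above or below the control values, as had 2697 of all genes (14.7%), where chance gives 10% for 3 against 3. The number of features past the threshold was 31, 18 and 16 without control arrays 1, 2 and 3, and 13, 295 and 38 without homocysteine arrays 1, 2 and 3. PMCH, TRIM16, LMF1 and ENTPD1 passed whichever array was left out, while 15 of the 39 named genes that passed did so in only 1 of the 6 reduced sets.

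Genes of the dividing cell were lower after homocysteine. All 31 measured mitosis and G2/M genes had a lower mean, with a median log2 difference of −0.54. None passed over all features, and 18 passed, all lower, when adjusted over the list alone. HMMR, a spindle protein, differed by −1.09, DLGAP5 by −0.76, PRC1 by −0.75 and the cyclin CCNB2 by −0.87. The S and G2 phase cyclin CCNA2 differed by −0.58 (adjusted p = 0.254 over all features, 0.0383 adjusted over the list alone). Camera placed the list below the other genes (adjusted p = 4.21e-18), with adjusted p = 0.55 with an estimated correlation. The mean of the list relative to the controls was −0.22, −0.40 and −1.01 on homocysteine arrays 1, 2 and 3, and between −0.12 and 0.12 on the control arrays. Without homocysteine array 3 its median was −0.30, and PRC1 differed by −0.48, CCNB2 by −0.53 and CCNA2 by −0.34.

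The replication-dependent histone genes had a median difference of −0.27, with 28 of 29 members lower. None passed over all features or when adjusted over the list alone. H1-1 differed by −0.76 and H2BC14 by −0.75. The list's camera adjusted p was 3.98e-08, against adjusted p = 0.70 with an estimated correlation. Without homocysteine array 3 the median was −0.10 and H2BC14 differed by −0.46. Without homocysteine array 2 the median of the list was −0.43 and H2BC14 differed by −1.01. Of 32 DNA replication and G1/S genes 30 were lower, with a median of −0.19. None passed over all features, and PRIM1, a primase subunit (−0.58), and RRM1, a subunit of ribonucleotide reductase (−0.48), passed when adjusted over the list alone. By camera this list had an adjusted p of 4.37e-08, with adjusted p = 0.68 with an estimated correlation, and its median was −0.12 without homocysteine array 3.

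Interferon-stimulated genes were higher after homocysteine in 28 of 32 measured members, with a median difference of 0.17. IFI6 rose by 0.81, the ubiquitin ligase HERC6 by 0.73 and OAS2, a sensor of double-stranded RNA, by 0.54. These 3 passed over all features, and 8 members passed, all higher, when adjusted over the list alone. OAS1 was among those 8 with a difference of 0.44. Camera's adjusted p was 1.13e-07, with adjusted p = 0.44 with an estimated correlation, and the median was 0.11 without control array 1. Among antigen presentation genes, 8 of 12 measured members were higher and the median was 0.20. None passed over all features. The immunoproteasome subunits PSMB8 (0.50) and PSMB9 (0.41) and the peptide transporter subunit TAP2 (0.37) passed when adjusted over the list alone. Camera gave adjusted p = 0.006, with adjusted p = 0.68 with an estimated correlation. Without homocysteine array 2 the adjusted p was 0.134.

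Of the oxidative stress lists, NRF2 targets and glutathione genes had a median of 0.18, with 17 of 22 members higher. None passed over all features, and 6 passed, all higher, when adjusted over the list alone. They included AKR1B10, an aldo-keto reductase (0.58, from a low level of 5.41), TXNRD1, thioredoxin reductase (0.44), SRXN1, sulfiredoxin (0.37), and the quinone reductase NQO1 (0.33). By camera the adjusted p was 3.76e-06, with adjusted p = 0.55 with an estimated correlation. HMOX1, heme oxygenase, differed by 0.33 (adjusted p = 0.328). Metallothioneins, which bind zinc and copper, were lower in 10 of 10 measured members, with a median of −0.18. The estimated correlation between these genes was 0.56, so the 10 are not independent results. Whether their probes also read each other's transcripts was not tested. MT1F fell by 0.66, and 4 members passed, all lower, when adjusted over the list alone. MT1E differed by −0.52, MT1M by −0.30 and MT1X by −0.28. For metallothioneins camera's adjusted p was 6.56e-06, with adjusted p = 0.55 with an estimated correlation, and the median was −0.11 without homocysteine array 1. Neither the antioxidant enzymes (camera adjusted p = 0.546) nor the heat shock response (adjusted p = 0.925) passed. SOD2, the mitochondrial superoxide dismutase, differed by 0.52 and passed only when adjusted over the list alone.

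Arterial and flow-regulated genes changed in part. In the list of shear stress, KLF and Notch genes, CXCR4, GJA4 and SOX17, a transcription factor of arterial endothelium, rose, the last by 0.61. GJA5, another arterial gap junction protein, fell by 0.95. The other 15 of 19 measured members did not pass over all features, and 7 members passed when adjusted over the list alone, 6 higher and 1 lower. The median was 0.21 and camera's adjusted p was 0.000296, with adjusted p = 0.55 with an estimated correlation. THBD, thrombomodulin, differed by 0.21 (adjusted p = 0.451).

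Among endothelial identity genes, SOX17 and the tight junction protein CLDN5 (0.62) rose. CD34 (0.46), the growth factor receptor KDR (0.44) and von Willebrand factor, VWF (−0.54), passed only when adjusted over the list alone. The list as a whole had a median of 0.041 over 30 members and did not pass (camera adjusted p = 0.123, and 0.04 without control array 1), and the median was 0.019 without control array 2. Of 22 coagulation and fibrinolysis genes, ENTPD1 and coagulation factor gene F5 fell, F5 by 0.56. VWF also passed when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.681).

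Genes of vascular tone included ADM, which encodes the vasodilator adrenomedullin and rose by 0.59. The endothelin gene EDN1 (0.37), ACE (0.41) and prostacyclin synthase, PTGIS (−0.77), did not pass over all features. When adjusted over the list alone, 5 of 26 members passed, 4 higher and 1 lower. NOS3, the endothelial nitric oxide synthase, differed by −0.04 (adjusted p = 0.952), and by 0.0078 and 0.0093 without control array 1 or homocysteine array 1. The median of the list was 0.041 and camera's adjusted p was 0.0272, with adjusted p = 0.55 with an estimated correlation. The call was lost without control array 2 (adjusted p = 0.0575), control array 3 (0.0796), homocysteine array 2 (0.0842) or homocysteine array 3 (0.0679), and the median lay between 0.011 and 0.091 over the 6 reduced sets.

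Of 29 inflammation and adhesion genes none passed over all features, and 5 passed when adjusted over the list alone, 4 higher and 1 lower. IL1B, which encodes a form of interleukin-1, differed by 1.71 (SE 0.36, adjusted p = 0.0862), with an SD of 0.86 between the 3 control arrays. The transcription factor JUN differed by 0.51, the adhesion receptor SELE by 0.54 and SELP by −0.60. ICAM1 (0.60), VCAM1 (−0.38) and the chemokine gene CCL2 (0.41) had adjusted p-values of 0.573, 0.781 and 0.254. ICAM1 differed by 0.89 without control array 2 and 0.29 without homocysteine array 2, and VCAM1 by −0.086 and −0.64. The median was 0.097 and camera's adjusted p was 0.0272, with adjusted p = 0.76 with an estimated correlation. Without homocysteine array 2 the median was −0.0012 and the adjusted p 0.634, and without control array 3 they were 0.051 and 0.278. The median was 0.24 without control array 2 and 0.18 without homocysteine array 1.

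**Figure D2:**
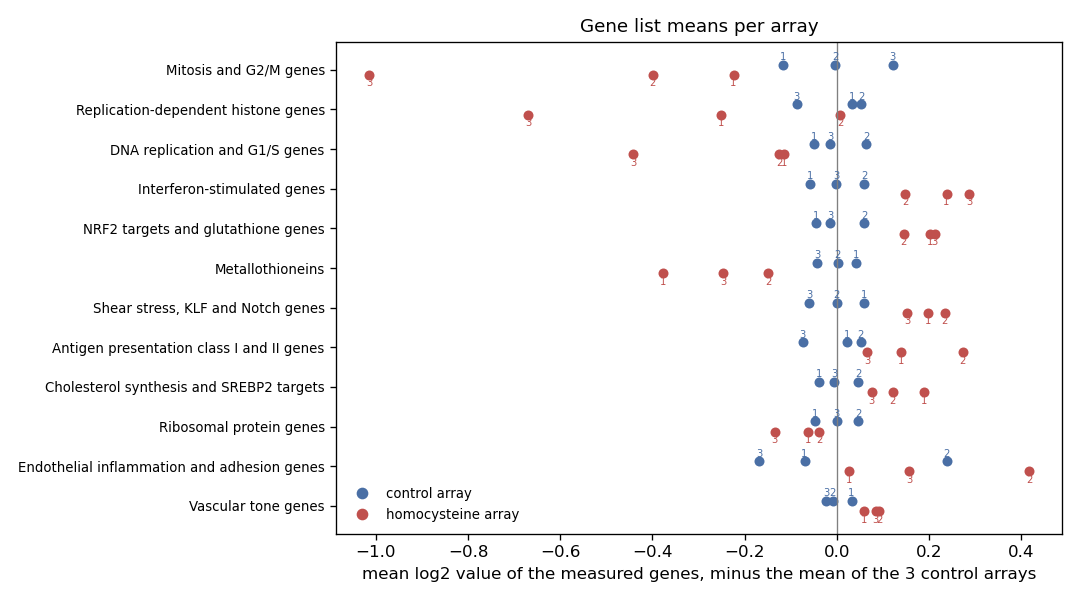
Each point is the mean log2 value of a list's measured genes on 1 array, minus the mean of the 3 control arrays, for the 12 gene lists past camera's threshold with its preset correlation. Blue points are control arrays, red points are homocysteine arrays and the small numbers are array numbers. Mitosis and G2/M genes reach −1.01 on homocysteine array 3, and the control and homocysteine points overlap for the histone, ribosomal protein, and inflammation and adhesion lists.

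Enzymes that make and remove homocysteine showed no member past the threshold over all features. CTH, which converts cystathionine to cysteine, differed by 0.43 (SE 0.16, adjusted p = 0.367). Methionine synthase, MTR, differed by −0.20, MAT2A, which makes S-adenosylmethionine, by 0.068, and AHCY, which releases homocysteine, by −0.11. Leaving out 1 array, these 3 ranged from −0.30 to −0.088, from 0.033 to 0.12 and from −0.19 to −0.021. PEMT, a phospholipid methyltransferase, differed by −0.75 and was the only 1 of 25 measured members to pass when adjusted over the list alone. The list had a median of 0.040 and did not pass (camera adjusted p = 0.901). Of the serine, glycine and one-carbon enzymes, MTHFD2L (0.60) passed only when adjusted over the list alone. That list had a camera adjusted p of 0.797.

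Amino acid and endoplasmic reticulum stress genes did not pass as lists with all 6 arrays. Among 28 ATF4 and amino acid response genes, VLDLR, a lipoprotein receptor, rose by 0.68 and 27 did not pass. ATF4 itself differed by 0.14, the asparagine synthetase gene ASNS by −0.26 and TRIB3 by 0.095, and TRIB3 by −0.040 without homocysteine array 2 and ASNS by −0.098 without control array 2. Camera's adjusted p was 0.404. None of 26 chaperones and unfolded protein response genes passed, with HSPA5, the main chaperone of the endoplasmic reticulum, at −0.11 and WFS1 at 0.59 (camera adjusted p = 0.966). None of 19 cytoplasmic aminoacyl-tRNA synthetases passed, and the list's camera adjusted p was 0.0912. It was 0.00373 without control array 2 and 0.0429 without homocysteine array 3, so this list is left open.

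Of the lipid lists, cholesterol synthesis genes were higher in 14 of 19 measured members, with a median of 0.11. None passed over all features, and the mevalonate kinase MVK (0.39) and the lanosterol synthase LSS (0.40) passed when adjusted over the list alone. Camera's adjusted p was 0.014, with adjusted p = 0.55 with an estimated correlation. Without homocysteine array 1 the adjusted p was 0.116, and without homocysteine array 2 the median was 0.069. The desaturases FADS1 (−0.39) and FADS2 (−0.46, and −0.30 without homocysteine array 3) did not pass, nor did any other of 16 fatty acid synthesis genes (camera adjusted p = 0.681).

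Hypoxia and glycolysis genes that rose were SLC2A1, the main glucose transporter of endothelium (0.87), ALDOC, an aldolase (0.78), and ADM. The other 26 of 29 did not pass, the median was 0.018 and camera's adjusted p was 0.0804. The list passed without control array 2 (median 0.047, adjusted p = 0.018) or homocysteine array 3 (0.036, adjusted p = 0.0429). Among 33 matrix genes, MMP1 and DCN, the proteoglycan decorin (0.87), rose and ADAMTS1 fell. LUM, the related proteoglycan lumican, differed by 0.91 from a low level of 4.685 and passed only when adjusted over the list alone. There 7 matrix genes passed, 4 higher and 3 lower. The matrix list had a median of −0.11 (camera adjusted p = 0.147, and 0.0168 with features below the median level left out), and of −0.053 without homocysteine array 1. None of 27 TGF-beta and BMP targets passed over all features, while SMAD6 (−0.52), BMPER (−0.43), ID1 (−0.67) and SMAD7 (−0.46) passed when adjusted over the list alone (camera adjusted p = 0.104, and 0.0196 without control array 3).

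Ribosomal protein genes had a median of −0.077, with 17 of 24 lower, and none passed over all features or when adjusted over the list alone. RPL11 differed by −0.34. Camera's adjusted p was 0.0272, with adjusted p = 0.76 with an estimated correlation. The call was lost without control array 2 (adjusted p = 0.247) or homocysteine array 3 (adjusted p = 0.251), and the median was −0.12 without homocysteine array 2 and −0.036 without homocysteine array 3. Among 26 ribosome biogenesis and MYC targets IMPDH2 fell, and among 11 small nucleolar RNAs and hosts SCARNA9 fell by 1.06, while neither list passed (both camera adjusted p = 0.393). Without control array 1 the small nucleolar RNAs had a median of −0.31 (adjusted p = 6.14e-06). No gene of the mitochondrial respiratory chain, the autophagy and lysosome list or the DNA and histone methylation machinery passed over all features. Their camera adjusted p-values were 0.0912, 0.057 and 0.29. Without control array 2 they were 0.00328 and 0.00773 for the respiratory chain and autophagy lists, and the methylation list was at 0.0443 without homocysteine array 1. DNMT1, the maintenance DNA methyltransferase, differed by −0.17 (adjusted p = 0.768), and by −0.26 and −0.050 without homocysteine arrays 2 and 3. CASP9 (0.61) passed among 19 apoptosis regulators, and CCNG1 (−0.37) and TP53I3 (0.42) among 23 p53 targets, only when adjusted over the list alone. Camera's adjusted p-values for these lists were 0.546 and 0.434.

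Markers of other cell types did not pass as lists with all 6 arrays. Smooth muscle and pericyte markers had a median of −0.074 (camera adjusted p = 0.061), with ACTA2, smooth muscle actin, at −0.45. That list passed without control array 3 (median −0.039, adjusted p = 0.0472), homocysteine array 2 (0.0267), or control array 1 and homocysteine array 2 together (0.0411), and its median was −0.012 without homocysteine array 1. Fibroblast markers had a median of −0.0021 (adjusted p = 0.546), between −0.059 and 0.031 with 1 array left out, although DCN, which is also a matrix gene, rose, and LUM (0.91) passed when adjusted over the list alone. Among leukocyte markers FCER1G, an immune receptor chain, rose by 0.63 from a low level of 5.45, and the list did not pass (adjusted p = 0.696). No epithelial or mesothelial marker passed over all features, and the keratin KRT7 (−0.83) passed when adjusted over the list alone (list adjusted p = 0.703).

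Camera with its preset correlation passed 12 of 36 lists, 7 higher and 5 lower, at an adjusted p under 0.05. With the correlation estimated from the data, 0 lists passed, 2 had an unadjusted p under 0.05, and the smallest adjusted p was 0.44. Fry, which asks whether a list's genes move on balance 1 way, passed 0 lists, with 7 at an unadjusted p under 0.05. Fry in either direction, which asks whether any of a list's genes move and not whether they move together or more than other genes, passed 17 lists. Exact permutation of 3 against 3 arrays cannot give a p under 0.1. Median and camera direction differed in sign for the antioxidant, heat shock, endoplasmic reticulum, fibroblast and coagulation lists, and mean and direction for the heat shock and methionine cycle lists, none of which passed.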

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

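The features without a gene symbol entered only 1 alternative setting, and no result of the report is named from them, yet a signal appeared among them. When all features were tested together, 19 of the 5835 unnamed features passed limma's threshold, 13 higher and 6 lower after homocysteine. That share is smaller than the 129 of 26890 among all features. The 19 may not all be separate signals. A pair of them shared the same means (7.88 to 8.57). Falls from 8.29 to 7.45 and from 8.29 to 7.48 lay close to that of a called feature of the immunoglobulin gene IGKC (8.28 to 7.48). The largest difference was 1.80 on the log2 scale, on a feature that went from 4.37 to 6.17. The largest fall was −0.94, from 9.51 to 8.56. No explanation was tested, since the annotation used here does not name these features.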

How the results depend on the processing

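The first residual component as a covariate, and leaving out control array 1 and homocysteine array 2 together, were chosen after seeing the data, and the other alternatives before the data were examined. Each of the 39 named genes past the threshold kept its sign under every alternative run for it (up to 19). This was fixed beforehand and is no further check. Their groups did not overlap, and renormalisation moved no feature by more than 0.0591. Together 496 checks kept the threshold and 231 lost it. The number of features past the threshold was 121. It stayed between 89 and 177 with quantile normalisation, median centring, filters on dim features, unnamed features added, a variance trend, a 1.5-fold limit, or control array 1 and homocysteine array 2 left out (177 features, 90 of them shared with the 121). It was 641 with array weights and 765 with the residual component, both of which kept all 121. The residual component leaves every fold as it was and only narrows the spread, by its construction. The number past the threshold was 13 when tested against a 1.2-fold change. It was 0 without moderation, where limma's fit left 1862 features at an unadjusted p under 0.05. Moderation adds 5.53 prior degrees of freedom, drawn from all features, and the test without it lacks them. The cause of the other shifts was not tested. With each array left out the number ranged from 13 to 295, the highest without homocysteine array 2, the array of lowest weight (0.394).

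The labels do not say whether the replicate numbers pair the arrays, and over all features most arrays did not follow the numbers. Deviations of same-numbered arrays correlated at −0.523, −0.011 and 0.488, and 2 of the 6 arrays correlated best with their own number. With the replicate block, 28 features and 11 lists passed, and the vascular tone list did not (adjusted p = 0.0512).

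The number of lists past camera's threshold was 12 and lay between 10 and 14 under all alternatives except an estimated correlation and fry, where it was 0. Of the checks on the 12 lists, 172 kept the threshold, 44 lost it and 0 turned. Apart from those 2 tests, only the cholesterol, antigen presentation, inflammation, vascular tone and ribosomal protein lists lost it. Alternatives also added 20 calls on 10 other lists and 121 on 50 other named genes, 83 of them with array weights or the residual component and 17 without homocysteine array 2. Lowest adjusted p-values were 6.14e-06 for small nucleolar RNAs, 0.00328 for the respiratory chain, 0.00373 for aminoacyl-tRNA synthetases and 0.00676 for autophagy with 1 array left out, and 0.0168 to 0.0443 for matrix, hypoxia, TGF-beta, smooth muscle, endothelial identity and methylation lists.

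Only results that did not pass turned direction, where for a list the direction is camera's and the value its median log2 difference, and the cause was not tested. The methionine cycle list turned with the replicate block (0.040), quantile normalisation (0.026), the filters at the 25th percentile (0.040) and the median (0.010), array weights (0.027), and the pair of arrays left out (0.0036). The endoplasmic reticulum list turned with quantile normalisation (−0.037), both filters (−0.025 and −0.0024) and the variance trend (−0.025). The heat shock list turned with quantile normalisation (0.0059) and both filters (−0.0060 and 0.016). The epithelial list turned with quantile normalisation (0.0054), the fibroblast list with the lower filter (−0.074) and the ATF4 list with the pair of arrays left out (−0.034). TRIB3 turned with array weights (−0.022) and with that pair left out (−0.059).

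Leaving out each array in turn, ranges that include a turn were −0.10 to 0.0093 for NOS3, −0.040 to 0.21 for TRIB3, −0.013 to 0.035 for the methionine cycle, −0.054 to 0.019 for the endoplasmic reticulum, −0.022 to 0.052 for heat shock, −0.083 to 0.036 for epithelial markers, −0.11 to 0.023 for leukocyte markers, 0.015 to 0.11 for ribosome biogenesis, −0.099 to 0.022 for one-carbon enzymes and −0.31 to 0.082 for small nucleolar RNAs. Leaving out 1 array moved 45 of 133 uncalled named genes by more than 1.5 times. Without a call of signal over background, changes of genes dim in a group, such as GKN2, FCER1G, LUM, AKR1B10 and PMCH, are less certain in size.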

Other observations

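The tests of homocysteine array 3 and of the array axis for the mitosis genes, of the shared target for IGKC, of the detection floor for PMCH and of neighbouring genes were chosen after the result was seen, and so were the genes named in the next paragraph and in the tests of IGKC, PARPBP, SPRY1 and DUSP16. For the mitosis genes, the limit of the array 3 test was tightened and an uninformative first form of the axis test was replaced, both after their results were seen. A first form of the floor test for PMCH used the gap between the groups, which the choice of the gene fixes, and was replaced in the same way.

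Some genes past the threshold lay beyond the fixed lists, and no grouping of them was tested. PGF, placental growth factor, rose by 0.75 on the log2 scale (adjusted p = 0.0217 by limma), while the receptor EGFR fell by 0.72. MGP, an inhibitor of calcification, fell by 0.71, and the integrin subunit ITGB4 fell by 0.96. NID2, a basement membrane protein, rose by 0.89. The phospholipid acyltransferase LPCAT3 rose by 0.73 and the kinase LYN by 0.72. EIF2B2, a subunit of the factor that recharges the translation initiation factor eIF2, rose by 0.87. PTGR1, a reductase of prostaglandins and leukotrienes, rose by 0.70. The histone gene H2BC12, which is on none of the lists, rose by 0.90, against a median of −0.27 for the replication-dependent histone list. RPL27A, a ribosomal protein gene that is also on no list, rose by 0.55 on its brighter feature, while its other feature differed by −0.035.

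The lower values of mitosis and G2/M genes were uneven between the treated arrays. Without homocysteine array 3, the median difference was −0.303 in place of −0.54, and the error of the difference between array means was 0.11, so this test does not decide whether the pattern rests on that array. For the array axis that separates control array 1 and homocysteine array 2 from the others, the slope within groups gives a prediction. It predicts a shift of 0.00897 (SE of this prediction 0.0963) in the list, which argues against the axis as the source. Slower division under homocysteine, cultures that differed in density at harvest, and array 3 alone also stay open and cannot be told apart with 3 arrays per group.

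Of 13 features named for IGKC, the immunoglobulin kappa constant gene, 4 passed the threshold, with falls of 0.79 to 0.88 on the log2 scale. The brightest IGKC feature differed by −0.02, so IGKC is not among the 108 genes. Cells of the B lineage in the control cultures would bring their other transcripts. The 11 B-lineage markers had a median difference of 0.0203 (SE of the mean over the markers 0.029). Their levels of 4.17 to 7.34 lay below the median of 7.70 of all features. No call says whether the markers held signal in the controls, so the limit set beforehand does not decide and such cells stay open. After subtracting group means, the lowest correlation between any 2 of the 4 features was 0.977 over the 6 arrays, consistent with 1 shared target read 4 times. A first version of this test took all 13 features, whose lowest correlation computed the same way is −0.799, and was replaced by the test on the 4 after that result was seen, so the shared target remains a hypothesis, and its nature was not tested.

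PMCH stood out in size, and its gene overlaps PARPBP. Transcripts of PARPBP differed by −0.353 (SE 0.18), opposite to PMCH, which argues against signal from that neighbour as the source. The homocysteine mean of 8.89 lay 1.18 above the median level of 7.70 of all features (SD 0.30 between arrays), which argues against noise near the floor in the homocysteine arrays, while the control level may be background. An effect of homocysteine on PMCH is a hypothesis that these data leave open, and cross-hybridisation of its probes with other transcripts was not tested.

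SPRY1 and DUSP16, feedback inhibitors of kinase signalling, rose by 0.69 and 0.59. A candidate explanation is higher output of the ERK pathway. A set of 14 feedback and target genes of that pathway, which leaves out SPRY1 and DUSP16, had a median difference of −0.0109. Their mean was 0.0268 (SE over the genes 0.066, which are not independent replicates), with 6 higher and 8 lower. Limma passed 0 of them, with PHLDA1 nearest at 0.62 (adjusted p = 0.052) and 4 at an unadjusted p under 0.05. The values argue against a general rise of these 14 transcripts at 48 h, and the activity of the pathway itself was not measured.

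A further hypothesis was that genes changed in 1 direction lie side by side in the genome, as ABCA9 and ABCA6 do. Pairs of such genes starting within 500 kb of each other numbered 5, against a mean of 2.58 in 10000 random draws (permutation p = 0.123), so clustering was not shown.

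The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 of the 10 splits, the real one, called as many as its 121 features, and the highest of the other splits called 2. For lists, 2 of the 10 called as many as the real 12, and the highest other called 16. That other split set control arrays 1 and 3 with homocysteine array 3 against the rest. The other splits called between 4 and 16 lists. Each of them sets 2 arrays of 1 group with 1 of the other, so only part of a treatment difference remains in it. A remaining part alone does not account for a split with 16 lists, more than the real 12. Camera at its preset correlation thus also called lists on differences between arrays that do not follow the treatment. How many of the 12 lists are such calls is not measured by these counts.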
